A study of Capsicum chinense with 23 samples.

How the data were processed

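RNA from inoculated leaves of Capsicum chinense 'PI152225' was sequenced on an Illumina HiSeq system, per the series' design text, in 23 libraries that the labels place in 8 groups by inoculum (mock or TSWV), day (1 or 5 dpi) and temperature (25 or 30 °C). The submitters' processing notes name FastQC 0.10.0, Trimmomatic 0.36, TopHat2 2.0.13, DESeq2 and Cufflinks, the last 2 without a version. The role of each tool, the genome build beyond the scaffold names and the strandedness are not given in the sources used here. Where reads of near-identical copies were split, the values of such coding sequences are uncertain.

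The deposited values are FPKM (fragments scaled by coding length and by the number of mapped fragments) per coding sequence, made by the authors, in a table with the layout of a Cufflinks tracking file, per the file headers. It has 1 column of values per group over its pooled replicates, a lower and an upper interval bound and a status word. The interval bounds are symmetric around the value and stop at 0, and their level is not given in the sources used here. The columns with no day in their name were read as 5 dpi, because the others are marked as 1 and the labels have these 2 days. All values printed for single groups are the authors' pooled values. The authors' deposited gene models (annotation v1.2) give positions, which are printed 1-based on the scaffolds of that annotation. All of their coding lengths are multiples of 3, so lengths are called coding lengths.

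Of 35002 coding sequences, 4 whose status was not OK in a group were left out, 9196 were listed at 0 in every group, and 14142 reached 1 FPKM in at least 1 group. Gene models were matched by identifier for 34996. The table of reference gene names for this species matched 0 of the identifiers, and the gene models carry no descriptions. The 29 gene lists fixed for pathways and cell type markers therefore could not be applied, and no list has a result. The rule for named coding sequences, fixed before the data were examined, allows without descriptions at most 2 identifiers that rose and 2 that fell. These are the 2 largest changes in each direction for TSWV against mock at 5 dpi and 25 °C among those at least 2-fold apart with at least 5 FPKM in the higher group, and they were followed through all groups. The choice of this comparison for the rule, and all regions given by position, were chosen after their values were seen.

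The design fixed before the data were examined was a limma test over the libraries, with no test if the table held 1 value per group. The latter applied. Values were log2(FPKM + 1) with a pseudocount of 1, over coding sequences with at least 1 FPKM in a group of the comparison, and those at least 2-fold apart were counted. The 10 comparisons were TSWV against mock (4), 30 against 25 °C (4), and the difference between temperatures in the TSWV effect (2). Overlaps between contrasts that share no library were set against the number expected for independent lists over the coding sequences counted in both. No expected number was computed for opposite changes. A shared count above its expected number therefore does not show by itself that changes kept their direction. Medians of sets were set against 10000 random lists of the same size (2000 for temperature contrasts and single-exon shares) matched on mean level in 20 bins, as a description of these columns. Neighbours are coding sequences next to each other on a scaffold among those counted, with overlapping gene models and shared loci left out, and a run holds at least 3. Alternatives were a pseudocount of 0.1, no filter on low values, rescaling of the columns by the median ratio to the geometric mean, a 4-fold threshold, and intervals that do not overlap.

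Whole reads could not be recovered. With a tolerance of 0.1 of a step, at most 21.5 to 23.9% of low values times coding length were whole in the 8 columns, against 20% by chance, so the depth is unknown and no counting interval is given. The counting step was tested on simulated data with 2 groups drawn from the mock group at 5 dpi and 25 °C. With noise of 0.1 on the log2 scale, over 11295 coding sequences, 100% of 4-fold risers and 100% of 4-fold fallers were recovered and 0% of unchanged ones were counted. With noise of 0.3, over 11561, these were 100, 98 and 0.739%. The changes were put only into coding sequences with at least 5 FPKM, and the noise was chosen, not estimated from these data. The authors' intervals are wide, with a median half-width of 66.1 to 79.2% of the value. The simulation thus checks the code and gives no rate of false counts for the comparisons here. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.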

Results

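The data were leaf transcriptomes of the pepper Capsicum chinense 'PI152225', a line with resistance to tomato spotted wilt virus (TSWV), a virus carried by thrips. The series title names the question as the breakdown of this resistance at high temperature. Inoculated leaves had received mock inoculum or TSWV, were kept at 25 or 30 °C, and were taken 1 or 5 days post inoculation (dpi). Leaves with local necrosis were the ones taken at 5 dpi, per the labels. The 23 libraries form 8 groups of 3, except that mock at 1 dpi and 25 °C has 2. The deposited table gives 1 FPKM value per coding sequence and group, with the replicates pooled, so no value has a standard deviation and no difference was tested against the spread between replicates. The error given beside a value is the authors' interval, whose level is not given in the sources used here. The intervals are wide, with a median half-width of 66.1 to 79.2% of the value in the 8 groups. Between 10896 and 11562 coding sequences reached 1 FPKM in a group, and the column totals ran from 417470 to 745682 FPKM. Sequencing depth is unknown from these values. In what follows, a coding sequence rose or fell when it differed at least 2-fold on the log2(FPKM + 1) scale, as a description and not as a test. Changes are on that scale, which understates the change of low values. Coding sequences are named by the identifiers of annotation v1.2 or by their position on its scaffolds, since the files do not pair them with gene names.

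TSWV against mock at 5 dpi and 25 °C showed how inoculated leaves differed at the lower temperature once local necrosis was present. With a pseudocount of 1, the largest rise among coding sequences with at least 5 FPKM was that of CC.CCv1.2.scaffold785.35, on scaffold 785 from 1014594 to 1015070 on the minus strand, with 1 coding exon of 477 bases. It went from 0.589 FPKM in mock to 538 FPKM (interval 304 to 772) with TSWV, a log2 change of 8.41. The next was CC.CCv1.2.scaffold528.92, with 2 coding exons between 1676071 and 1676591 on scaffold 528, which went from 2.20 to 559 FPKM, a log2 change of 7.45. Its interval with TSWV ran from 0 to 1276 FPKM and overlaps that of mock. The largest fall at that pseudocount was that of CC.CCv1.2.scaffold11.13, 1 coding exon of 636 bases from 3864127 to 3864762 on scaffold 11, from 121 FPKM (62.2 to 179) to 8.46 FPKM (3.90 to 13.02), a log2 change of -3.68. CC.CCv1.2.scaffold242.165, with 132 coding bases between 2424004 and 2424522 on scaffold 242, went from 26.8 to 1.197 FPKM, a log2 change of -3.66, with intervals that overlap.

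**Figure D1:**
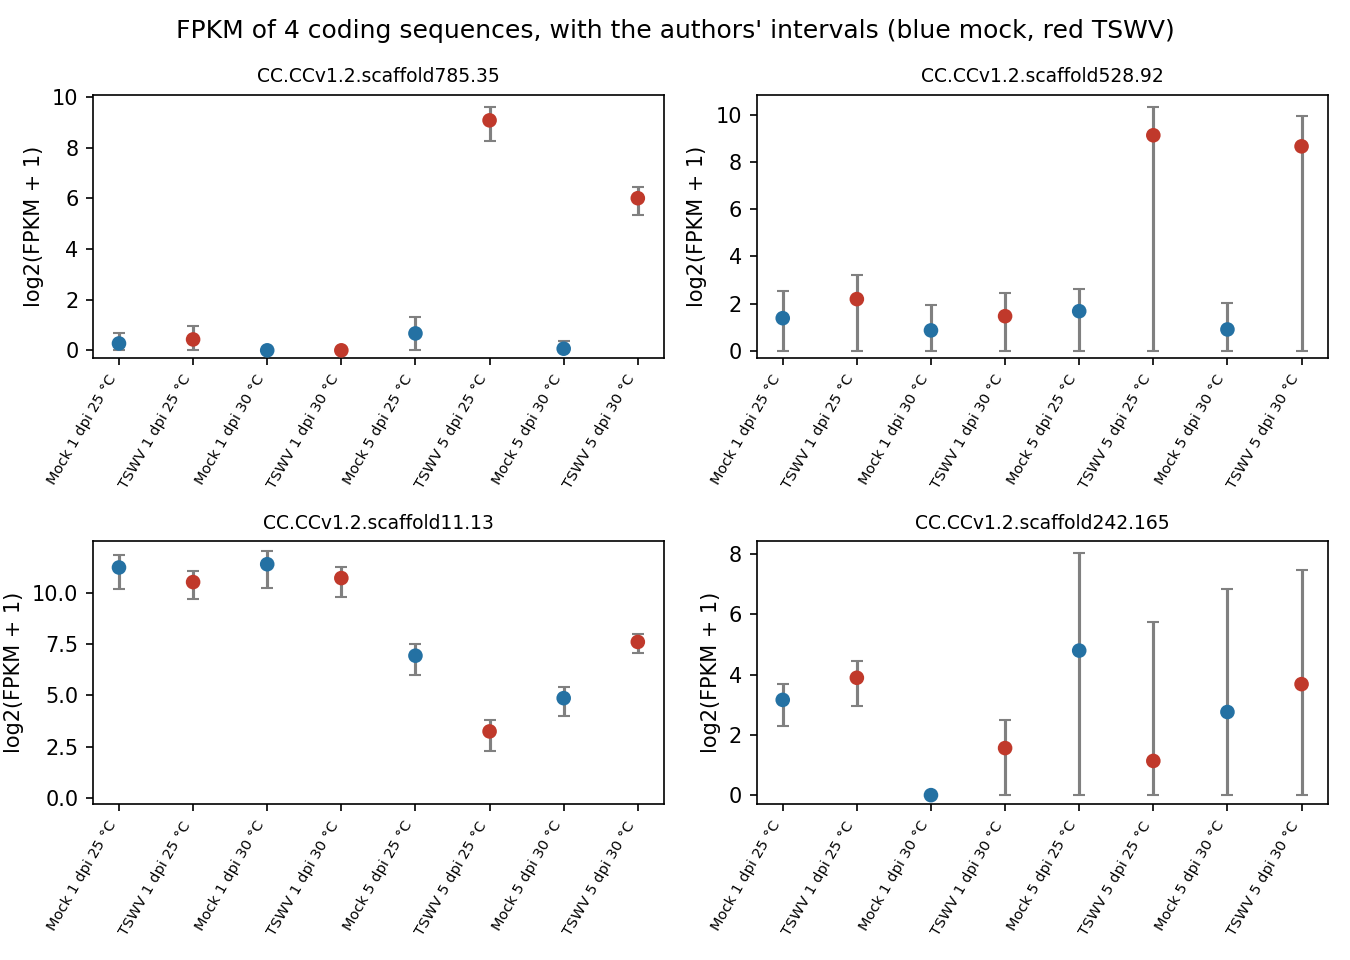
FPKM of the 4 coding sequences named by the fixed rule, as log2(FPKM + 1), in the 8 groups (blue mock, red TSWV); bars are the authors' intervals. CC.CCv1.2.scaffold785.35 is above 60 FPKM in the TSWV groups at 5 dpi and below 1 FPKM in the other 6 groups, and CC.CCv1.2.scaffold11.13 lies below mock with TSWV at 25 °C and above mock at 30 °C at 5 dpi.

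Neighbouring coding sequences rose together in several regions, which were singled out after their values were seen. On scaffold 935, all 7 coding sequences between 207186 and 317674 rose, with a median log2 change of 5.47. Of these, 6 have 1 coding exon, and their coding lengths are 669 to 870 bases. They stood at 0.206 to 6.03 FPKM in mock and at 5.89 to 295 FPKM with TSWV, and the intervals of all 7 were apart. On scaffold 1119, 4 neighbours of 471 to 480 coding bases between 78375 and 269468 had a median log2 change of 2.92. On scaffold 494, 4 neighbours between 863128 and 933050 had a median of 2.41, and on scaffold 525, 5 neighbours between 1372378 and 1516488 had a median of 2.16. Runs of neighbours fell as well. The longest was of 7 coding sequences on scaffold 823 between 77811 and 152919, with a median of -1.54. On scaffold 832, 4 single-exon coding sequences of 318 to 324 bases between 43162 and 71258 had a median of -1.85. Among abundant transcripts, the coding sequence at 430781 to 431863 on scaffold 679 went from 32.9 to 3012 FPKM (1186 to 4839), a log2 change of 6.47. The coding sequence at 442918 to 444470 on scaffold 1039 had the highest value among those that rose, 16374 FPKM against 1245 in mock, but its interval with TSWV ran from 0 to 46434.

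Over the 12405 coding sequences with at least 1 FPKM in either group, 1376 rose and 579 fell at 5 dpi and 25 °C. At 4-fold, 439 rose and 42 fell. The authors' intervals did not overlap for 697 higher and 158 lower coding sequences. The share expected by chance cannot be given without the level of the intervals. Among coding sequences with at least 5 FPKM in both groups, rescaling by the median ratio took the median log2 ratio from 0.06 to -0.05. This log2 ratio has no pseudocount. After rescaling the columns, 1194 coding sequences rose and 698 fell. Of the coding sequences that rose, 26.2% had 1 coding exon, against 17.4 to 21.7% in 95% of 2000 random lists matched on mean level, and of those that fell 29.9% did, against 15.9 to 22.5%. Both sets were short: the median coding length was 963 bases for those that rose, against 1030 to 1114.5 in 95% of 10000 matched lists, and 726 bases for those that fell, against 918 to 1038.

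At 5 dpi and 30 °C, the same contrast was asked at the higher temperature. CC.CCv1.2.scaffold785.35 went from 0.0456 to 63.1 FPKM (39.4 to 86.8), a log2 change of 5.94. CC.CCv1.2.scaffold528.92 went from 0.874 to 404 FPKM, a log2 change of 7.75, again with overlapping intervals. CC.CCv1.2.scaffold11.13 rose from 28.0 FPKM (14.7 to 41.3) to 192 FPKM (130 to 255), a log2 change of 2.74, opposite in direction to 25 °C. CC.CCv1.2.scaffold242.165 was at 5.77 FPKM in mock and 11.9 FPKM with TSWV, with overlapping intervals. The 7 coding sequences on scaffold 935 rose again, with a median log2 change of 4.33, to 1.17 to 66.1 FPKM with TSWV, and the intervals of 6 were apart. With the next neighbour they formed a run of 8 up to 359149. The 4 neighbours on scaffold 1119 had a median of 2.72 and the coding sequence at 430781 to 431863 on scaffold 679 went from 81.9 to 1391 FPKM (674 to 2107). A run of 4 coding sequences on scaffold 785 between 710565 and 759074 had a median of 1.86 at 30 °C and of 1.45 at 25 °C. On scaffold 791, 5 neighbours between 490033 and 512228 fell, with a median of -1.36, where their median at 25 °C was 0.48. The coding sequence at 752129 to 752820 on scaffold 679 went from 6862 FPKM (1446 to 12277) in mock to 810 FPKM (499 to 1121) with TSWV, a log2 change of -3.08.

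Of 12185 coding sequences at 5 dpi and 30 °C, 655 rose and 389 fell. At 4-fold, 190 rose and 38 fell, and the intervals were apart for 320 higher and 78 lower. Of those that rose, 36.9% had 1 coding exon, against 17.3 to 23.2% in 95% of the matched random lists, and of those that fell 21.1% did, within 16.5 to 24.4%. After rescaling, 650 rose and 365 fell.

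**Figure D2:**
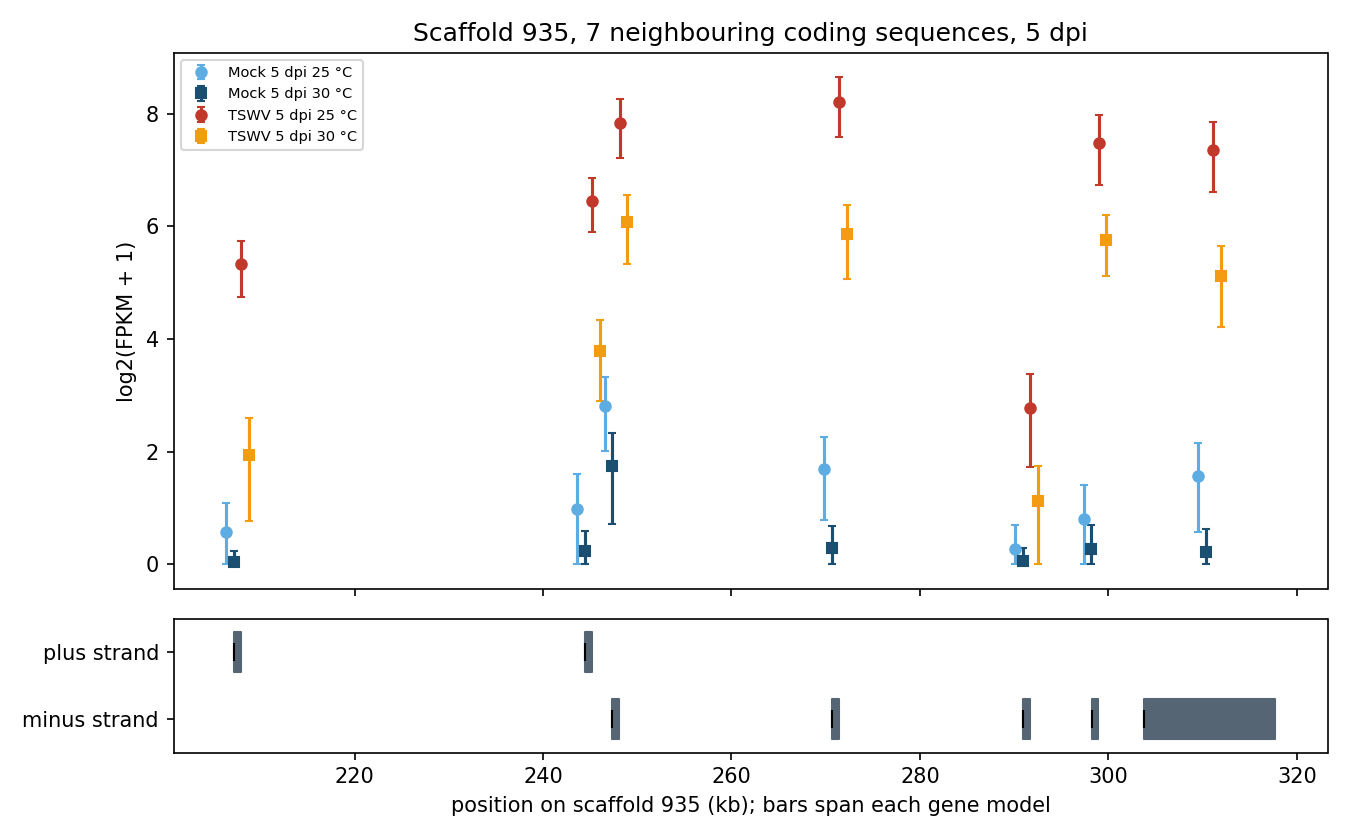
The 7 neighbouring coding sequences on scaffold 935 at 5 dpi, as log2(FPKM + 1) with the authors' intervals in the upper panel (points of 1 coding sequence are set slightly apart), and their gene models by strand along the scaffold in kb in the lower panel. All 7 were higher with TSWV than in mock at both temperatures, with medians of 5.47 at 25 °C and 4.33 at 30 °C on the log2 scale.

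The response to TSWV at both temperatures was set side by side at 5 dpi, which is the comparison the series title points to; these contrasts share no library. Of the 11483 coding sequences with at least 1 FPKM in both, 395 rose at both temperatures, 6.4 times the 61.7 expected for independent lists. Among these 11483, they are 66.7% of the 592 that rose at 30 °C and 33.0% of the 1197 that rose at 25 °C. The shares are smaller over all 655 and 1376 that rose, which include coding sequences below 1 FPKM at the other temperature. Of those that fell, 41 fell at both temperatures against 14.5 expected. Opposite changes occurred in both directions: 46 fell at 25 °C and rose at 30 °C, and 46 rose at 25 °C and fell at 30 °C. The 1376 that rose at 25 °C had a median change of 0.47 at 30 °C, above the random lists, 95% of which lay between -0.03 and 0.01. In the other direction, the 655 that rose at 30 °C had a median change of 1.46 there and of 1.497 at 25 °C. The 579 that fell at 25 °C had a median of 0.01 at 30 °C, above the range of 95% of the random lists (-0.07 to 0). The 389 that fell at 30 °C had a median of -0.0067 at 25 °C, below that range (-0.0019 to 0.11). Of the 11 runs of neighbours that fell at 25 °C, 7 had a median above 0 at 30 °C and 4 a median below 0, from -0.53 on scaffold 528 to 0.99 on scaffold 832. The run of 7 on scaffold 823 had a median of 0.51.

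The difference between the TSWV effects at 30 and 25 °C was at least 2-fold for 2316 of 13107 coding sequences at 5 dpi, with 1403 lower and 913 higher at 30 °C. Of the 1403, 795 had risen at 25 °C, 122 of which rose at both temperatures, and 259 fell at 30 °C, with 46 counted in both classes. The remaining 395 were 2-fold apart at neither temperature. Of the 913, 398 had fallen at 25 °C and 192 rose at 30 °C, with 46 counted in both, and 369 were 2-fold apart at neither temperature. On scaffold 791, 4 neighbours between 762819 and 938685 had a median of 1.39 at 25 °C and of -0.57 at 30 °C. CC.CCv1.2.scaffold11.13 was in the higher set. These counts are a description without a test, and rescaling gave 1142 lower and 1069 higher.

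**Figure D3:**
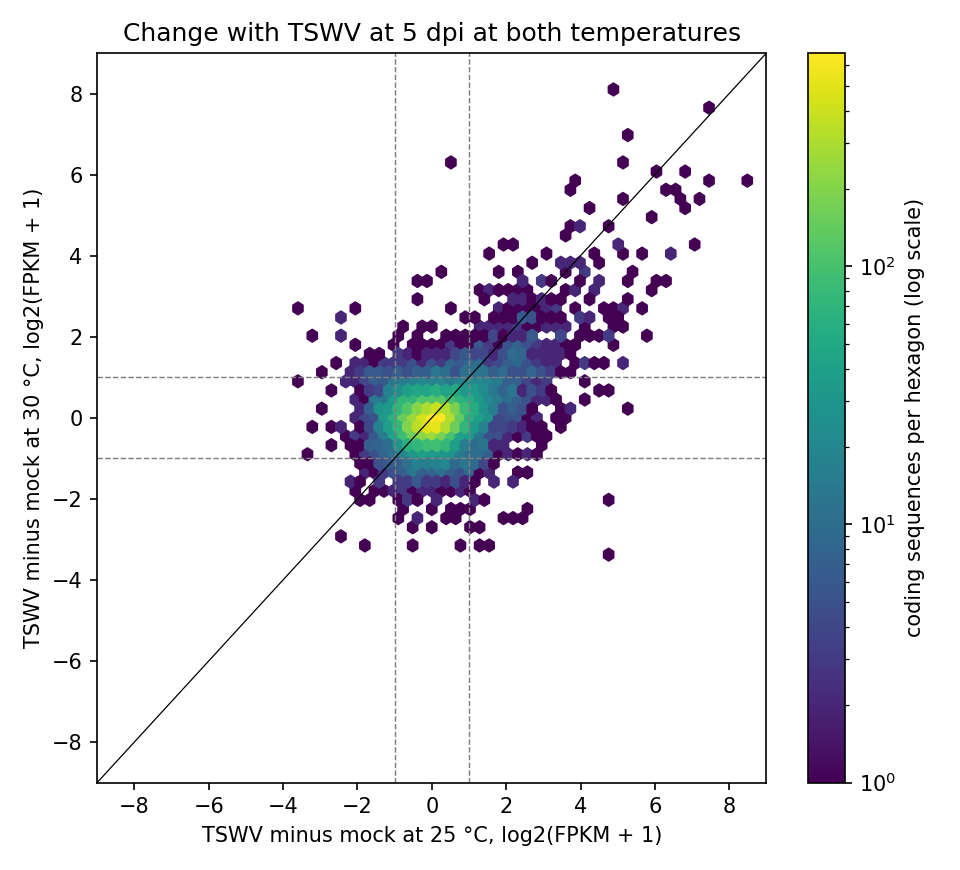
Change with TSWV at 5 dpi at 25 °C (x axis) and 30 °C (y axis), both as differences of log2(FPKM + 1), for 11483 coding sequences; colour is the number per hexagon on a log scale, dashed lines mark 2-fold and the solid line equal change. Of these, 395 lie past the upper dashed lines on both axes and 41 past the lower ones.

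At 1 dpi, the inoculation contrasts asked which transcripts differed before necrosis was sampled. CC.CCv1.2.scaffold785.35 was below 0.5 FPKM in all 4 groups and CC.CCv1.2.scaffold528.92 was at 3.57 FPKM or less. CC.CCv1.2.scaffold11.13 stood at 1456 to 2661 FPKM in the 4 groups, with overlapping intervals between mock and TSWV. CC.CCv1.2.scaffold242.165 differed between TSWV and mock by 0.73 at 25 °C and by 1.56 at 30 °C, where it was listed at 0 in mock, with overlapping intervals in both. On scaffold 525, 3 of the 5 neighbours that rose at 5 dpi had already risen at 1 dpi and 25 °C, and the 5 had a median of 1.56 at 25 °C and of 0.22 at 30 °C. The 7 coding sequences on scaffold 935 had medians of 0.30 at 25 °C and 0.13 at 30 °C, and none rose. On scaffold 823, the 7 neighbours that fell at 5 dpi and 25 °C had medians of -0.94 and -1.03 at 1 dpi at 25 and 30 °C. The 4 neighbours on scaffold 925 between 76814 and 385474 had a median of -1.06 at 25 °C and of 1.98 at 30 °C. The coding sequence at 752129 to 752820 on scaffold 679 went from 51.0 FPKM (27.5 to 74.5) to 605 FPKM (274 to 935) with TSWV at 30 °C, the opposite of its change at 5 dpi.

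At 25 °C and 1 dpi, 275 of 12010 coding sequences rose and 424 fell, and at 30 °C, 227 of 11746 rose and 312 fell. With a pseudocount of 0.1 the excess of falls at 30 °C was gone, with 610 that rose and 602 that fell, and at 25 °C 684 rose and 762 fell. The intervals were apart for 24 higher and 29 lower at 25 °C and for 9 higher and 14 lower at 30 °C. Between temperatures, 20 rose in both against 3.22 expected and 87 fell in both against 7.09 expected. Opposite changes occurred too: 10 rose at 25 °C and fell at 30 °C, and 22 fell at 25 °C and rose at 30 °C. The 312 that fell at 30 °C had a median coding length of 451.5 bases, against 946.5 to 1131 bases in 95% of matched lists. Between days at 25 °C, 61 rose at both 1 and 5 dpi, against 20.53 expected, and 8 rose at 1 dpi and fell at 5 dpi. Of falls at 25 °C, 37 were shared by both days, against 13.35 expected, and 28 fell at 1 dpi and rose at 5 dpi. At 30 °C, 17 rose at both days, against 7.20 expected, and 20 rose at 1 dpi and fell at 5 dpi. More of these rises thus turned than were shared, and the correlation between the days at 30 °C was -0.03 across genes. Of falls at 30 °C, 23 were shared by both days, against 5.49 expected, and 15 fell at 1 dpi and rose at 5 dpi. The 227 that rose at 1 dpi and 30 °C had a median of -0.14 at 5 dpi and 30 °C, below all 10000 random lists. The 1376 that rose at 5 dpi and 25 °C had a median of 0.14 at 1 dpi and 25 °C, and 65.5% of them were higher with TSWV there. The difference between temperatures in the TSWV effect at 1 dpi was at least 2-fold for 968 of 12606 coding sequences, with 546 higher and 422 lower at 30 °C.

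The temperature contrasts within mock and within TSWV asked what 30 °C changed with the inoculum held fixed. CC.CCv1.2.scaffold11.13 was lower at 30 °C in mock at 5 dpi, by -2.07 on the log2 scale, and higher with TSWV, by 4.35, with intervals apart in both. CC.CCv1.2.scaffold785.35 was lower at 30 °C with TSWV at 5 dpi, by -3.07, with intervals apart, and CC.CCv1.2.scaffold528.92 differed by -0.47 there. CC.CCv1.2.scaffold242.165 was lower at 30 °C at 1 dpi with intervals apart, by -3.16 in mock and by -2.33 with TSWV. In mock it was at 7.95 FPKM (3.94 to 11.96) at 25 °C, a group of 2 libraries, and listed at 0 with an interval of 0 to 0 at 30 °C. Against that interval any lower bound above 0 counts as apart, so its separation in mock carries little weight. At 5 dpi it differed by -2.04 in mock and by 2.55 with TSWV, with overlapping intervals. In mock at 1 dpi, the single-exon coding sequence of 171 bases at 673578 to 673748 on scaffold 771 was at 26600 FPKM (12264 to 40936) at 25 °C and at 4282 FPKM (2879 to 5684) at 30 °C, a log2 change of -2.63. With TSWV it changed by -1.29, with overlapping intervals. In mock at 5 dpi, the coding sequence at 752129 to 752820 on scaffold 679 was at 740 FPKM (312 to 1169) at 25 °C and at 6862 FPKM at 30 °C. The coding sequence at 442918 to 444470 on scaffold 1039 was lower at 30 °C with TSWV at 5 dpi, at 3991 against 16374 FPKM, and higher in mock, at 3602 against 1245 FPKM, with overlapping intervals in both.

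In mock at 1 dpi, 175 coding sequences rose and 428 fell from 25 to 30 °C, and with TSWV 158 rose and 335 fell. Both contrasts shared 25 that rose against 1.34 expected and 64 that fell against 7.58 expected. In opposite ways, 10 rose in mock and fell with TSWV, and 19 fell in mock and rose with TSWV. At 5 dpi, 501 rose and 400 fell in mock, and 446 rose and 907 fell with TSWV, with 59 and 70 shared against 14.3 and 20.8 expected. Changes also went opposite ways: 60 rose in mock and fell with TSWV, and 44 fell in mock and rose with TSWV. No expected number was computed for these, so the shared counts do not show a common temperature response. The correlation between these contrasts was 0.05 across genes, which are not independent replicates. The intervals were apart for 13 higher and 82 lower in mock at 1 dpi, 9 and 66 with TSWV at 1 dpi, 114 and 97 in mock at 5 dpi, and 136 and 297 with TSWV at 5 dpi. Rescaling raised the median log2 ratio, without a pseudocount, of coding sequences with at least 5 FPKM in both groups. In mock at 1 dpi this median went from -0.11 to 0.02. With TSWV it went from -0.14 to -0.03 at 1 dpi and from -0.09 to 0.02 at 5 dpi. After rescaling, 217 rose and 380 fell in mock at 1 dpi (from 29.0 to 36.3% that rose). With TSWV, 213 rose and 289 fell at 1 dpi (from 32.0 to 42.4%), and 523 rose and 721 fell at 5 dpi (from 33.0 to 42.0%).

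**Figure D4:**
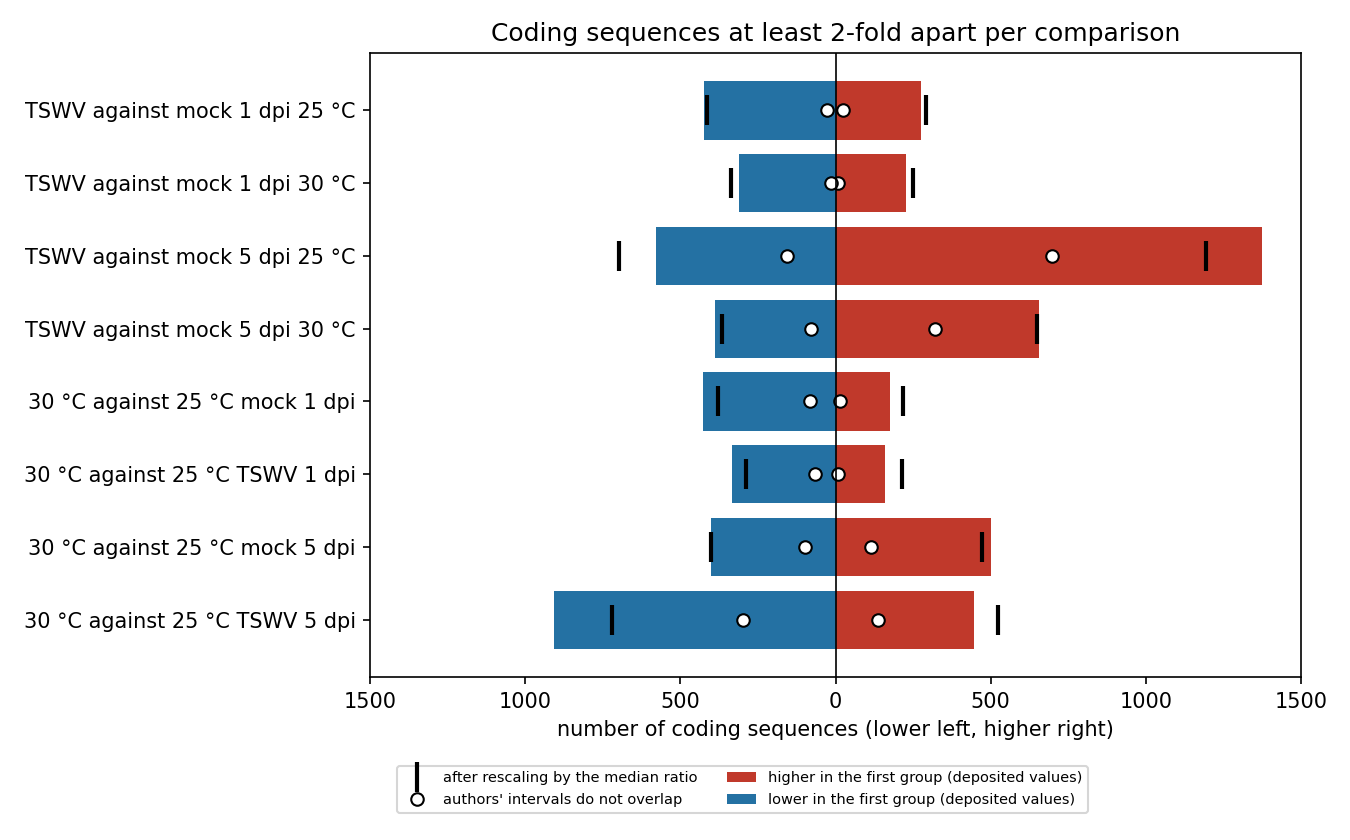
Number of coding sequences at least 2-fold higher (red, right) or lower (blue, left) in the first group of each of the 8 contrasts between 2 groups; ticks give the numbers after rescaling and circles those whose intervals did not overlap. TSWV against mock at 5 dpi and 25 °C has the highest number that rose, 1376, against 655 at 30 °C.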

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

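No paired analysis was possible because the table holds 1 pooled value per group and no test was run. For the same reason the planned fits over compared groups alone, without a trend, with a replicate block, and without each replicate were not run, nor were the gene list alternatives, and intervals are not defined for the difference between temperatures. Depth limits cannot be given. Causes of the changes below were not tested, except that a 4-fold threshold and separate intervals keep fewer coding sequences and a smaller pseudocount enlarges changes of low values by construction.

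Counts are given in the order TSWV against mock at 1 dpi 25 °C, 1 dpi 30 °C, 5 dpi 25 °C and 5 dpi 30 °C, then 30 against 25 °C in mock at 1 dpi, TSWV at 1 dpi, mock at 5 dpi and TSWV at 5 dpi, then the difference between temperatures at 1 and 5 dpi. The main counts were 699, 539, 1955, 1044, 603, 493, 901, 1353, 968 and 2316. A pseudocount of 0.1 gave 1446, 1212, 2958, 1871, 1290, 1155, 1777, 2323, 2010 and 3704. At 4-fold they were 54, 53, 481, 228, 88, 33, 98, 194, 112 and 413. The balance of TSWV against mock at 1 dpi and 30 °C turned with the pseudocount of 0.1, from 227 higher and 312 lower to 610 and 602. The intervals were apart for 53, 23, 855, 398, 95, 75, 211 and 433 in the first 8. No filter on low values and rescaling kept all 10 within 1.5 times the main count. The filter could not change the first 8, since a value under 1 FPKM cannot be 2-fold apart with a pseudocount of 1. At 4-fold, the median at 30 °C of those that rose at 25 °C was 1.37 in place of 0.47, and the median at 25 °C of those that rose at 30 °C was 3.01 in place of 1.497. Those that fell at 30 °C by 4-fold had a median of 0.22 at 25 °C, opposite in sign to -0.01 for all that fell. The 4 named coding sequences kept the direction of their 5 dpi changes under a pseudocount of 0.1 and rescaling, but not their rank: with 0.1, CC.CCv1.2.scaffold785.35 ranked 2 and CC.CCv1.2.scaffold528.92 ranked 14 among rises at 25 °C, and CC.CCv1.2.scaffold242.165 (-4.38) ranked 5 and CC.CCv1.2.scaffold11.13 (-3.82) ranked 7 among falls.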

Other observations

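The tests of scaling, of fallen genes at 1 dpi, of chance adjacency, of overlapping gene models and of FPKM ratios between neighbours (with its parts) were chosen only after their results were seen. The test of risen genes by their level in mock replaced one by the level of the higher group, whose result had been seen and which the rise itself affects. For the common factor, the shared source of reads and the pairs of unlike coding length, the bounds were preset, but the spread used to read the value against them was added after the values were seen and changed how all 3 were read. Chance selection of the genes that rose was also examined, through the medians at the other temperature given above.

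Very few short coding sequences made up much of the FPKM total of the 5 dpi columns. Since FPKM is scaled by coding length, these are not shares of reads. On scaffold 620, 3 single-exon coding sequences of 249 to 258 bases between 22901 and 76041 held 3.66 to 7.39% of the FPKM total in the 4 groups at 1 dpi and 12.4 to 30.7% at 5 dpi. The highest share was that of TSWV at 5 dpi and 25 °C, where the first of them reached 146221 FPKM, and the lowest at 5 dpi was mock at 30 °C. This order is uncertain, since intervals were wide. The one starting at 75784 was at 39566 FPKM (0 to 139550) in mock at 5 dpi and 25 °C. The one starting at 51891 was at 15333 FPKM (0 to 79221) with TSWV at 5 dpi and 25 °C. On scaffold 8, a coding sequence of 105 bases at 8621269 to 8621373 went the other way over the days. In mock at 25 °C it went from 71359 FPKM (23999 to 118719) at 1 dpi, a group of 2 libraries, to 7059 FPKM (0 to 15920) at 5 dpi. In mock at 30 °C it went from 20677 FPKM (0 to 42809) to 7198 FPKM.

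By the count of coding sequences at least 2-fold apart, the mock columns differed more between days than from TSWV at either day. In mock leaves, 3044 coding sequences were at least 2-fold apart between 5 and 1 dpi at 25 °C (1512 higher and 1532 lower at 5 dpi), and 3249 at 30 °C (1877 and 1372). At both temperatures 959 were higher at 5 dpi, against 214 expected for independent lists, and 902 lower, against 159 expected. CC.CCv1.2.scaffold11.13 was among the latter, with 2384 FPKM in mock at 1 dpi and 25 °C and 121 FPKM at 5 dpi. Day and harvest date or batch cannot be separated by this design.

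More coding sequences rose with TSWV at 5 dpi at 25 °C than at 30 °C, 1376 against 655. Scaling between columns is argued against as the whole cause, since the ratio after rescaling was 1.84 (1194 against 650). Noise in low values is argued against too, since among the 4363 coding sequences with a mean of at least 10 FPKM over the mock groups at 5 dpi the ratio was 2.53 (255 against 101). A uniformly smaller share of responding tissue at 30 °C may account for part of it and stays open. The 679 coding sequences that rose at 25 °C with intervals apart were used, a selection that can lower the factor. The median ratio of their rises at 30 to 25 °C was 0.249, with quartiles of 0.094 and 0.518. The predicted range was built from the outer interval bounds, which makes misses rarer. With 1 common factor of 0.249, 81 of the 679 (11.9%, Wilson 95% interval 9.70 to 14.6%) missed the predicted range. The value is past the preset bound of 10%, but close to it. The Wilson interval treats coding sequences of the same pooled columns as independent. It does not measure the spread between replicates, so the test cannot decide. A temperature effect on the response is the biological explanation in the design and remains untested, as replicates were pooled.

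Coding sequences that fell with TSWV at 5 dpi and 25 °C did not fall at 30 °C as a set. Short or low genes are argued against as the only source, since the result held without them. The 180 with at least 10 FPKM in mock and at least 600 coding bases had a median of 0.085 at 30 °C, and 11 of them fell there. Their median of -1.23 at 25 °C follows from their selection. Noise in these 180 themselves is not excluded, since falls by noise at 25 °C would also be absent at 30 °C. Of all 579 that fell, 154 had intervals apart. Chance selection alone is argued against by the separate 1 dpi libraries, where the set had medians of -0.19 at 25 °C and -0.26 at 30 °C, below all 2000 random lists matched on level and coding length (lowest -0.13 and -0.18). The lists drew coding sequences singly, while the set holds runs of neighbours that vary together, so their range may be too narrow. The 1 dpi values do not show why the set did not fall at 5 dpi and 30 °C. A shared source of reads, such as repeated copies, could lie behind the 11 runs of falling neighbours: across the 6 columns not used to choose them, genes on different scaffolds had a median pairwise r of 0.71, against 0.03 for 200 random fallen genes and 0.42 for runs of risen neighbours. Leaving out 1 run at a time gave 0.62 to 0.77, around the preset bound of 0.7, and after centring each day the fallen runs had 0.45, below the 0.64 of the risen runs, so this cannot be told apart from a shared response over these few columns.

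Coding sequences that rose at 5 dpi and 25 °C lay side by side in 219 pairs, more than in any of 2000 random draws matched on level (mean 136, highest 168). Overlapping gene models are argued against as the cause, since the count without them was 213, 209 of them among the 219. The highest random draw was then 169. This was not particular to these rises. Without overlapping models, falls at 5 dpi and 25 °C formed 54 pairs (highest draw 39) and falls at 1 dpi and 25 °C 28 (highest 26). Rises at 5 dpi and 30 °C formed 69 (highest 54). Rises at 1 dpi and falls at 30 °C lay within the draws. For the rises at 5 dpi and 25 °C, reads shared between near-identical neighbours are a candidate explanation that the test favoured. Their pairs whose coding lengths differ by over 1.5 times numbered 84, within 95% of the random draws (66 to 99, all draws 53 to 114). However, duplicated neighbours that respond together would give the same count. Copies that split the same reads would keep 1 ratio in all groups, and on scaffold 935 the ratio moved beyond the authors' intervals in 9 of the 21 pairs. Among them were all 8 pairs between the first 4 and the last 2 coding sequences. That division was made after the ratios were seen, so 8 of 8 describes these pairs and is not a separate test. A full split of the same reads would not move their ratios, but sharing of only part of the reads was not examined. In mock at 1 dpi and 25 °C the fourth was at 34.1 FPKM (22.1 to 46.2) and the sixth at 0.319 FPKM (0 to 0.836), against 295 and 178 FPKM with TSWV at 5 dpi and 25 °C. The other pairs of that run (1 of 13 moved) and most like-length pairs elsewhere stay open, since 26 of all 129 such pairs moved.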
